A study of Arabidopsis thaliana with 3 samples.

How the data were processed

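Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where FHY3 sits on the genome of Arabidopsis thaliana. The plants carried a FHY3 protein tagged with FLAG and HA, expressed from the 35S promoter in the fhy3-4 mutant, and grew under 16 h of light and 8 h of dark. Inflorescences with flowers up to stage 8 were collected, and chromatin was precipitated with an anti-FLAG antibody. The series holds 3 samples: 2 ChIP samples, described by the submitters as separate biological replicates, and 1 input sample of DNA without antibody. Samples were grouped by their titles. Each ChIP sample came with a peak list of its own, so peaks were called per sample and not on pooled reads. Values of the input sample were not used here, nor was the control without antibody that the series design mentions.

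Per the submitters' processing notes, CASAVA 1.8, Bowtie2 2.2.3 and MACS 1.4.2 were used. Their settings, the control given to the peak caller and the genome build are not given in the sources used here. The deposited lists hold a start, an end and a score per peak, and have no header. The scale of the authors' score is not stated, and it ran from 23.03 to a ceiling of 3100 in both lists. It was therefore used only to rank, filter or describe peaks within a list. The lists hold no reads, so sequencing depth is unknown and no value per peak carries a counting error. A deeper library gives more and higher-scored peaks, which can shift the numbers of peaks and the share found in the other list. Intervals given for shares are 95% Wilson intervals and cover counting error of peaks only.

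Starts were converted to positions counted from 1. Peaks on the 5 nuclear chromosomes were analysed, and organelle peaks were counted apart. Peaks of both lists that overlapped by at least 1 bp were joined into a shared peak spanning their union, with the best score from each list. Overlap and position were tested by a permutation test in which peak positions were redrawn, with 1000 random placements of each list within its chromosomes and widths kept (for overlap one-sided; the smallest p these can give is 0.001, and 0.002 for the two-sided tests of position). Local placement moved each peak by at most 500 kb. Each peak was redrawn on its own, so the SD and p-values of placement count neighbouring peaks as independent. Scores of overlapping pairs were compared by Spearman's rho and by Pearson's r of log10 scores, with permutation tests of 100000 resamples, for which the smallest p is 1e-05 for correlations and 2e-05 for medians. Tables of counts were tested with Fisher's exact test. Multiple tests were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

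Gene names and gene neighbourhoods came from a table of the TAIR10.1 assembly with 27444 protein-coding nuclear genes, without strand or sequence. No source used here names the build of the peak lists. Every statement that sets a peak beside a gene assumes that both share the frame of TAIR10.1, and positions printed are those of the peak lists. Shifting the peaks along the chromosomes did not settle this, as described with the closing observations. Because strand was not known, a gene was taken as next to a peak when the peak midpoint lay inside its span or within 1000 bp of either end. Midpoints were classed as inside a gene, outside but within 1000 bp, or farther away, in place of promoter, untranslated, coding and intron classes. Distance to a gene end of at most 500 bp took the place of distance to a transcription start. Gene-poor bins were 500 kb bins with a protein-coding gene density under 0.5 times the median of their chromosome. The planned searches for the FHY3 binding site, for other motifs and for all short words, and the relation of the binding site to score, need sequence and were not run.

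The tests, the alternatives, 12 gene lists with 225 distinct genes and the rule for named genes were fixed before the data were examined. All 225 locus identifiers were found in the gene table. The rule names the genes at the 20 shared peaks with the best summed rank of both scores among peaks with a gene, every list member next to a shared peak, and members of the floral organ, meristem and reported-target lists with a peak in a single list. The order fixed for assigning a gene, promoter, then gene body, then downstream, needs strand. In its place the gene holding the midpoint was taken, otherwise the gene with the nearest end within 1000 bp. Alternatives were a reciprocal overlap of 50%, midpoints within 200 bp, a score of at least 100, peaks at or above the median score, local placement, each replicate alone, other distances and bins, and other rules for assigning genes. Splits by gene-poor and other bins and by chromosome, shares near chromosome ends, gene families, comparisons at matched score, shifts of coordinates and the comparison of reported targets with housekeeping genes were added after the data were seen. A first form of the comparison at matched score set raw scores of both lists side by side; it was replaced because the lists need not share a scale.

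The procedures were tested on simulated data, with 100 simulations each. Independent lists of about the real size gave an overlap p under 0.05 in 3% of simulations, and 200 planted shared peaks gave one in 100%, with a mean excess of 189 peaks. Random sets of about 882 peaks gave a p under 0.05 in 3% of simulations for the share inside genes and in 1% for the share in gene-poor bins. Moving 100 peaks into genes was detected in 78%. Simulated peaks were drawn singly, as placement does, so the error rates for clustered peaks such as the real ones are not known. A list of 20 genes with 5 planted members had an unadjusted Fisher's exact p under 0.05 in 100% of simulations, and one with none planted in 1%. Fewer planted members, and adjustment over several lists, were not simulated, so the power for the real lists is not known.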

Results

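The data were 2 lists of FHY3 peaks from inflorescences of Arabidopsis, one for each ChIP replicate. FHY3 is a transcription factor of far-red light signalling that derives from a transposase. Replicate 1 had 1477 peaks, of which 1475 lay on the nuclear chromosomes, with a median width of 906 bp and 1641 kb covered in all. Replicate 2 had 1361 peaks, 1354 of them nuclear, with a median width of 953 bp and 1534 kb covered. The authors' median score was 42.8 in replicate 1 and 55.4 in replicate 2, and 385 and 491 nuclear peaks scored at least 100. The series compares no conditions, so the comparisons are between the replicates and between peaks and genes, and depth is unknown. Splits by gene density or chromosome, tests at matched score, widths at the score ceiling and reported targets against housekeeping genes were chosen after the data were seen.

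The first comparison asked which binding regions were found in both replicates. Most peaks were: 922 of 1475 peaks of replicate 1 (62.5%) overlapped a peak of replicate 2, and 904 of 1354 (66.8%) the reverse. Together they formed 882 shared regions, 294 of them on chromosome 1, 126 on chromosome 2, 167 on chromosome 3, 121 on chromosome 4 and 174 on chromosome 5. Random placement gave 36.2 ± 6.19 (SD) overlapping peaks for replicate 1 and 35.3 ± 5.98 for replicate 2 (placement permutation test, one-sided p = 0.001 for each, the smallest possible). Local placement raised the chance level to 103 and 100.1 peaks, still with a permutation p = 0.001. Overlap was lower in gene-poor bins, which held 639 peaks of replicate 1 and 478 of replicate 2: 47.4% and 61.5% were shared there, against 74.0% and 69.6% in the other bins. Local placement gave 12.8% and 16.4% in gene-poor bins and 2.57% and 2.43% in the others. Peaks in gene-poor bins also scored lower, with medians of 36.0 against 62.8 in replicate 1 and 35.3 against 107 in replicate 2. Overlap was not compared at matched score, so region and score cannot be told apart here.

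Peaks with high scores were nearly always found in both lists. In replicate 1 the shared part rose from 27.5% of peaks scoring under 30 (95% Wilson interval 23.3 to 32.0%) to 99.4% of those scoring from 100 to 200 (96.6 to 99.9%). In replicate 2 it rose from 34.2% (29.1 to 39.8%) under 30 to 100% of the 160 peaks scoring 500 or more (97.7 to 100%). The median score of shared and unshared peaks was 75.9 and 29.7 in replicate 1 and 117 and 32.1 in replicate 2 (permutation test, two-sided p = 2e-05 for each). Shared peaks were also wider, with medians of 976 and 700 bp in replicate 1 and 1081 and 705 bp in replicate 2 (permutation p = 2e-05 for each). Gene-poor bins held 60.8% of unshared peaks in replicate 1 and 40.9% in replicate 2 (Fisher's exact test between replicates, p = 4.26e-10). Of shared peaks they held 32.9% and 32.5% (Fisher's exact test against the unshared peaks of each list, p = 1.45e-25 and 0.00256). These tests count neighbouring peaks as independent, so the p-values may be too small.

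**Figure D1:**
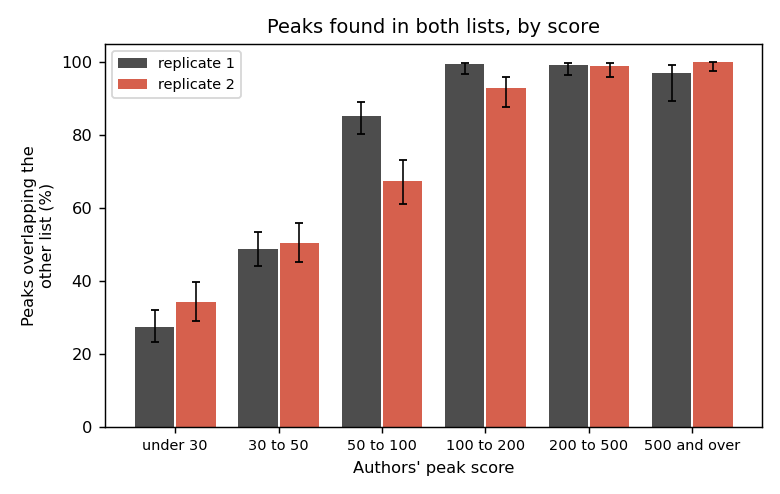
Percent of nuclear peaks that overlap a peak of the other list by at least 1 bp, by the authors' score, for replicate 1 (grey) and replicate 2 (red); error bars are 95% Wilson intervals. The share rises from 27.5% and 34.2% under a score of 30 to 96.9% and 100% at 500 and over.

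Ranks by score went together across the 944 overlapping pairs, with Spearman's rho of 0.821 and Pearson's r of 0.865 on log10 scores (permutation test, p = 1e-05 for each). This is a relation across peaks, which are not independent replicates. Within gene-poor bins rho was 0.568 and r 0.840 over 318 pairs, and in the other bins 0.881 and 0.880 over 626 pairs. The regions stood apart by rho and little by r, and the difference was not tested. Of the 8 peaks at the score ceiling in both lists, 6 lay in gene-poor bins. Shared peaks there had median scores of 47.0 in replicate 1 and 42.8 in replicate 2. Pairs so far above the rest can raise r, and r was not computed without them. The similar r values therefore do not show that scores agreed equally well in both regions. At a matched replicate 1 score of 50 to 100, the median replicate 2 score was 47.5 for gene-poor pairs and 137 for the others (permutation test, two-sided p = 2e-05). Matched by a replicate 2 score of 50 to 100, the median replicate 1 scores were 62.5 and 46.0 (permutation test, two-sided p = 0.00868). Both tests count neighbouring pairs as independent.

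**Figure D2:**
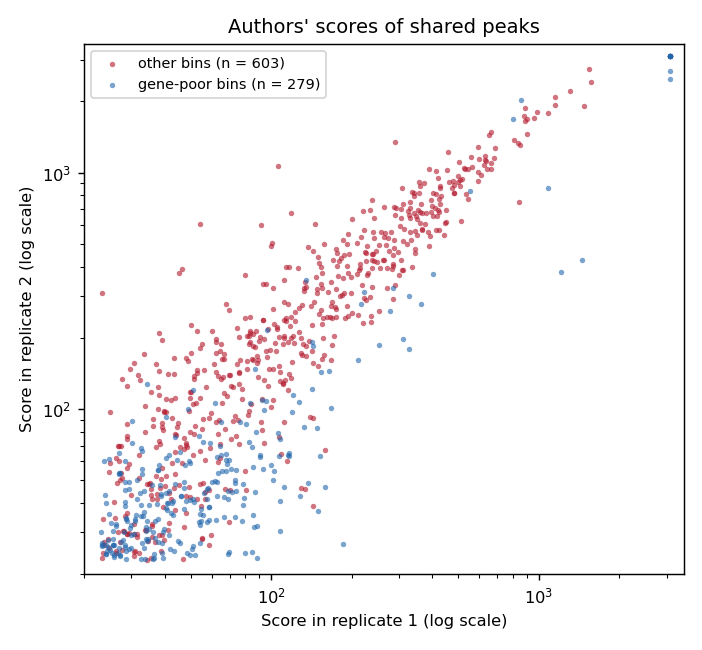
Authors' score of each shared peak in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), for 279 peaks in gene-poor bins (blue) and 603 in other bins (red). Scores of the lists need not share a scale; at the same replicate 1 score the gene-poor peaks lie lower on the replicate 2 axis, with medians of 46.1 (81 peaks) and 137 (130 peaks) for replicate 1 scores of 50 to 100.

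The next comparison asked where along the chromosomes the shared peaks lay. Gene-poor bins, which include the regions around the centromeres, held 279 of 882 shared peaks (31.6%), against 15.3 ± 1.22% (SD) by random placement (permutation test, two-sided p = 0.002, the smallest possible). The excess passed the threshold on chromosomes 1 and 5, with 150 of 294 and 53 of 174 shared peaks in gene-poor bins (chance 13.2% and 14.8%, placement permutation test, adjusted p = 0.005 for each). Chromosomes 2, 3 and 4 had 14.3%, 21.0% and 19.0%, against 17.8%, 17.0% and 16.2% by chance (permutation test, adjusted p = 0.455, 0.33 and 0.498). The densest stretch was chromosome 1 from 14 to 16 Mb, with 139 of the 294 shared peaks of that chromosome, against a median of 6 peaks per 1 Mb bin. Neighbouring peaks there can be close, such as those from 14743197 to 14743929 and from 14743994 to 14744626. Placement redrew each peak on its own, so the SD and p-values may be too small where peaks are pieces of 1 enriched stretch. The excess was made of low-scoring peaks. Of the 348 shared peaks with a score of at least 100 in both lists, 9.77% lay in gene-poor bins, below the 15.5 ± 1.92% of random placement (permutation p = 0.004). Among 540 shared peaks at or above the median score of each list the share was 15.0%, against 15.4% by chance (permutation p = 0.839). Among peaks of each list that were shared, median scores in gene-poor and other bins were 47.0 and 108 in replicate 1 and 42.8 and 203 in replicate 2 (permutation test, two-sided p = 2e-05 for each).

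**Figure D3:**
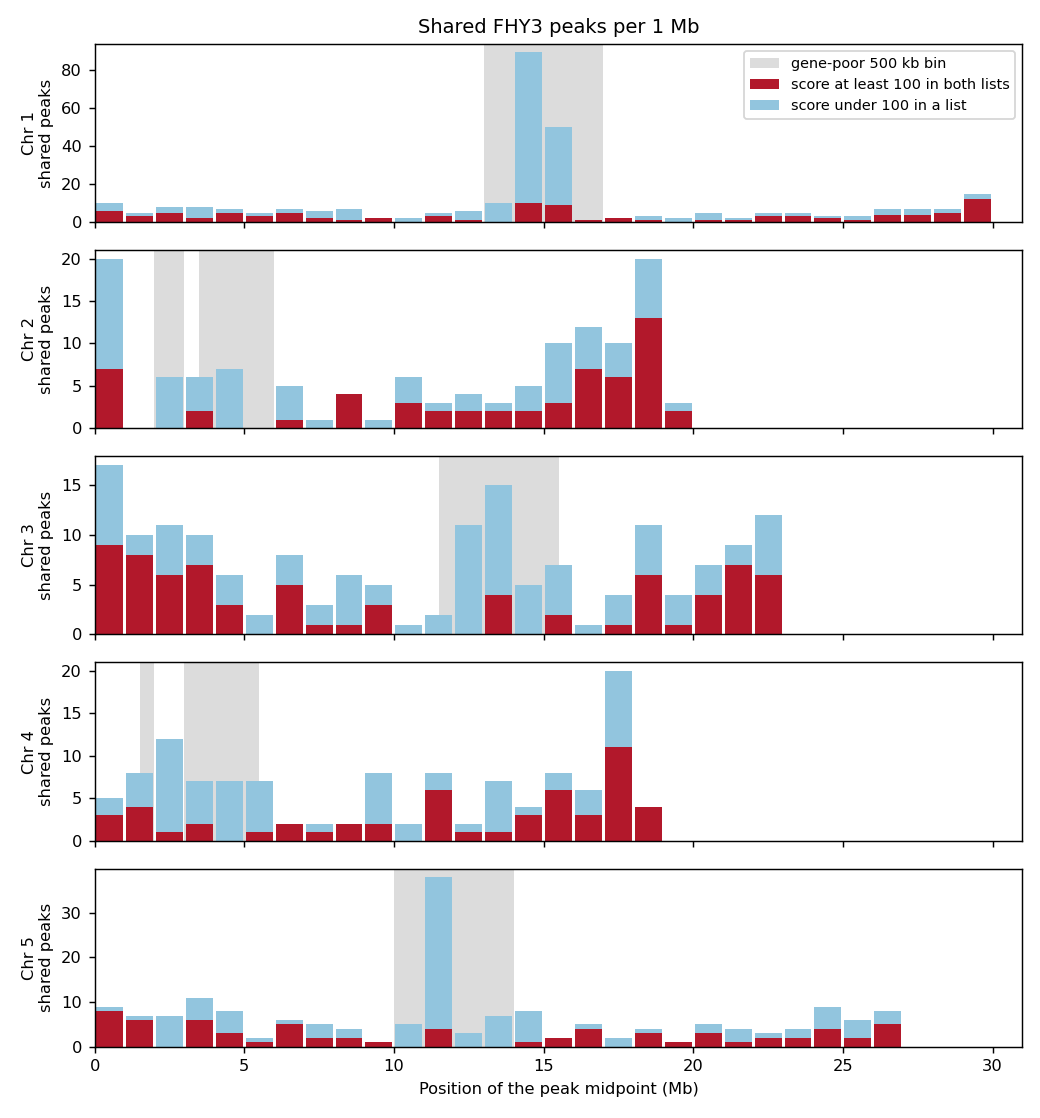
Shared peaks per 1 Mb along chromosomes 1 to 5, by the position of the peak midpoint in Mb, with peaks scoring at least 100 in both lists in red and the rest stacked in blue; grey marks gene-poor 500 kb bins, and the y axes differ. The highest bars are the bins of 89 and 50 peaks on chromosome 1, most of them low-scoring.

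The 8 peaks at the score ceiling in both lists were an exception among high scores. Of these, 6 lay in gene-poor bins, and 1, on chromosome 2 from 1004 to 10616, held 2 genes annotated as ribosomal RNA. They were 3855 to 16835 bp wide, with a median of 8422 bp, against 1160 bp for the other shared peaks (permutation test, two-sided p = 2e-05).

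Relative to protein-coding genes, 43.7% of the 882 shared midpoints lay inside a gene, 17.2% outside but within 1000 bp, and 39.1% farther away. Random placement along the chromosome gave 54.3 ± 1.65%, 20.4 ± 1.33% and 25.2 ± 1.46% (SD; permutation test, adjusted p = 0.003, 0.012 and 0.003). With local placement, the expected share inside genes was 45.7% (permutation test, adjusted p = 0.3), and for peaks scoring at least 100 the share was 57.5%, against 54.2% (adjusted p = 0.336). For the 603 outside gene-poor bins it was 59.9%, against 63.8% by local placement (permutation test, adjusted p = 0.075), a lower share that did not pass the threshold. Midpoints within 500 bp of a gene end made up 29.1%, against 35.4 ± 1.60% by placement along the chromosome (permutation p = 0.002) and 29.4% by local placement (p = 0.851). These shares and the gene names that follow assume the frame of TAIR10.1, since the build of the lists is not given in the sources used here, and strand was not used.

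Among the 20 best-ranked shared peaks with a gene, 14 midpoints lay inside a gene and 6 within 1000 bp of one, and 12 peaks without a gene were passed over on the way to the last of them. The ribosomal RNA peak of chromosome 2, beside AT2G01021, and a peak at AT3G32400 tied at the score ceiling in both lists. ABCC13 (AT2G07680), an ABC transporter gene, came next among peaks with a gene; AT3G32400, ABCC13 and AT4G03540 are in gene-poor bins. The ribosomal RNA peak lies outside the gene-poor bins; the next peaks with a gene outside them, by rank, lay at AT1G72250 on chromosome 1 from 27192974 to 27194688, with scores of 1569 and 2422 in replicates 1 and 2, and beside AHP2 (AT1G13330), a homolog of the meiotic protein HOP2, on chromosome 1 from 4567115 to 4568702, with scores of 1304 and 2220. The rest were AT5G04500, the beta-galactosidase gene BGAL14 (AT4G38590), AT2G40310, the peptidase gene TPP2 (AT4G20850), AT4G38480, AT3G49140, the B-box gene BBX16 (AT1G73870), SPX3 (AT2G45130) of phosphate signalling, the receptor-like kinase gene CRK3 (AT1G70530), AT4G38950, AT3G03140, the clock gene LNK1 (AT5G64170), AT1G76400 and AT1G77610. Scores were at least 651 in replicate 1 and 1274 in replicate 2 at all 20 peaks.

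The last comparison asked which genes of flower development, light signalling and related processes had a shared peak. In all, 689 of 27444 protein-coding genes (2.51%) were next to a shared peak, and 537 of the 882 peaks were next to a gene. Of the floral organ identity genes, 2 of 22 were: SEP2, a MADS-box gene that acts in all floral whorls, with a peak on chromosome 3 from 466913 to 468491 and scores of 349 and 546, and SHP2, a MADS-box gene of carpels and ovules, with a peak on chromosome 2 from 17818935 to 17820116 and scores of 427 and 733. PI and CAL had a low-scoring peak in replicate 1 only (28.8 and 33.5), and the other 18 had none. Of the meristem genes, 2 of 30 had a shared peak: HAM3, with scores of 483 and 816, and PHB, with 27.5 and 69.4. CUC1 had a peak in replicate 2 only (27.8), and 27 had none.

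In the other lists few members had a shared peak. These were PIF7 of 34 light signalling genes (scores of 161 and 246; the midpoint lies inside the neighbouring AT5G61260), LNK1 of 20 clock genes (661 and 1491), CHLH, a subunit of magnesium chelatase, of 28 tetrapyrrole genes (75.9 and 144), FRS3 of 14 genes of the FHY3/FAR1 family (187 and 309), and the phosphatase genes HAB2 (599 and 1140) and AHG3 (394 and 537) of 17 abscisic acid genes. None of 15 flowering time, 12 chloroplast division and 17 jasmonate genes did. Of 13 genes listed as reported FHY3 targets, SEP2 and ISA2 had a shared peak. The ISA2 peak scored 48.8 and 160, and its midpoint lies inside the neighbouring AT1G03290. ARC5 had a peak in replicate 1 only (26.2), and 10 had none. The origin of the reports is not given here, so a target reported from these same samples would be no independent check. Of 12 housekeeping genes, chosen for comparison, GAPC1 (167 and 343) and PP2AA3 did, but the midpoint of the GAPC1 peak lies inside GLR1.1, and PP2AA3 shares its peak with AHP2. With each peak given to its nearest gene at any distance, 679 genes had a peak, 522 of them also in the main count. By this rule 1 reported target and 0 housekeeping and light signalling genes had a peak. Jasmonate genes rose to 2 of 17 and abscisic acid genes to 3 of 17 (Fisher's exact test, adjusted p = 0.390 and 0.095).

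None of the 12 lists passed the threshold. The lowest adjusted p was 0.245 by Fisher's exact test and 0.852 by random placement, and the reported-target and housekeeping lists had unadjusted Fisher p of 0.0409 and 0.0352. Reported targets and housekeeping genes had a shared peak in 2 of 13 and 2 of 12 cases (Fisher's exact test, two-sided p = 1; 95% interval of the odds ratio 0.0561 to 14.8), so a difference of several-fold either way was not detectable with lists of this size.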

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

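Organelle peaks stand outside the comparisons of nuclear peaks, and no test of them was chosen after they were seen. Replicate 2 had 7 peaks on the mitochondrial genome, which was listed here because it is a signal outside the nuclear comparisons. Replicate 1 had 1 there and 1 on the plastid genome, and the difference between the replicates was not tested. The mitochondrial peaks of replicate 2 had scores from 30.3 to 115, and the highest lay from 252277 to 258824. The mitochondrial peak of replicate 1, from 329045 to 330742, overlapped the one of replicate 2 from 328605 to 330741. The plastid peak of replicate 1 ran from 1 to 8209 with a score of 98.7. Input reads over these positions were not analysed here, and no explanation was tested.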

How the results depend on the processing

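Alternatives that split or leave out gene-poor bins, chromosomes or peaks at the score ceiling were chosen after the data were seen. Overlap, score agreement and the differences between shared and unshared peaks kept their direction and their side of the threshold under all alternatives run. Results on position did not. For peaks scoring at least 100, 57.5% lay inside a gene, 21.3% within 1000 bp, 36.8% near a gene end and 9.77% in gene-poor bins, all in the opposite direction from the main result. Only the gene-poor share passed the threshold (permutation p = 0.004). The first 3 shares were near their chance levels of 54.2%, 20.4% and 35.4% (permutation test, p = 0.336 and 0.705, both adjusted, and 0.607). For peaks at or above the median score these were 53.9%, 20.6%, 35.6% and 15.0%, the first in the same direction and the others opposite, none past the threshold. With local placement the shares of 43.7%, 17.2% and 29.1% no longer differed from chance past the threshold, and the second changed direction. Outside gene-poor bins with local placement, the shares were 59.9%, 23.1% and 40.5%, none past the threshold and the last pair opposite in direction. A flank of 500 bp gave 11.6% near a gene, no longer past the threshold. The cause was not tested. Genes next to a shared peak numbered 365 with a score of at least 100 and 1337 with an interval of 3000 bp. No list passed the threshold in 8 alternatives, with lowest adjusted p from 0.0528 to 0.366. Of 96 counts of list members 11 changed direction, on 0 to 2 members: tetrapyrrole genes 0 with a score of at least 100; light signalling and jasmonate genes 1 each with any overlap; jasmonate genes 2 with 3000 bp; and light signalling 0, jasmonate 2 and housekeeping 0 with the nearest gene. With replicate 1 alone, floral organ identity genes had 4 members and reported targets 3 (Fisher's exact test, adjusted p = 0.0528 for both). With each replicate alone, light signalling and tetrapyrrole genes had 1 member each and chloroplast division genes from 0 to 1, and the share in gene-poor bins was 35.3 to 43.3%. Motif searches and transcription start classes were not run. No paired analysis was possible because the series has a single ChIP group. Unknown depth limits what the absence of a peak means.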

Other observations

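The tests of peaks near chromosome ends, of gene families, of coordinate shifts, at matched score, by chromosome and of overlap within gene-poor bins were chosen after the data were seen. High-scoring shared peaks crowded the ends of the chromosomes. Of the 348 shared peaks with a score of at least 100 in both lists, 121 (34.8%) lay in the outer 2 Mb, against 16.8 ± 2.03% (SD) by random placement (permutation test, two-sided p = 0.002, the smallest possible). All 10 chromosome ends had more such peaks than an even spread gives, from 7 peaks against 5.70 at the start of chromosome 4 to 17 against 5.69 at the end of chromosome 2. In 5 sets tested, the share was 21.9% of all shared peaks (chance 16.4%), 31.0% of those outside gene-poor bins (19.6%), 34.8% of the high-scoring, 37.9% of the high-scoring outside gene-poor bins (19.6%), each with a permutation p = 0.002, and 23.5% of the weaker ones outside gene-poor bins (19.8%, p = 0.166). With outer lengths of 1, 3 and 4 Mb the high-scoring share was 16.7%, 44.5% and 55.7%, which is 1.99, 1.78 and 1.67 times chance. Each list alone gave 31.9% and 30.1%, but the lists hold mostly the same high-scoring peaks.

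The ends of the arms are gene-rich, and gene density may draw peaks there. Protein-coding genes had 20.4% of their number in the outer 2 Mb, weighted by the peaks per chromosome, and the share of high-scoring peaks exceeded this by 7.07 SD of placement, which argues against gene density as the whole cause. Other properties that change along the arms were not tested, and no biological explanation was tested, since the design has a single ChIP group.

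Shared peaks scoring under 100 in a list crowded the gene-poor bins of chromosomes 1, 3, 4 and 5 (66.0%, 33.3%, 27.9% and 46.2% of them, against 13.2%, 17.0%, 16.3% and 14.8% by chance; permutation test, adjusted p from 0.00333 to 0.0425), and not detectably those of chromosome 2 (22.9% against 17.9%, adjusted p = 0.366). Independent chance calls spread evenly over the 500 kb to either side would overlap there only at the local chance level. The overlap was 3.70 times that level from replicate 1 and 3.75 times from replicate 2. On the single chromosomes it was 2.91 to 9.85 times (permutation test, one-sided p = 0.001 for each). These ratios argue against chance calls spread in that way. Chance calls crowding the same short stretches in both lists would also overlap above that level, so they cannot be told apart here. Neighbouring peaks were placed independently, so these p-values may be too small. A single signal scaled by 1 factor between the libraries would put gene-poor pairs level with the others, or lower whichever list is matched. Gene-poor pairs scored lower in replicate 2 at matched replicate 1 score (4 of 4 bands). At matched replicate 2 score they scored higher in replicate 1 (3 of 4 bands past the threshold, permutation test). The other band, 30 to 50 by replicate 2 score, had the same direction but did not pass (medians 43.3 and 39.7, permutation p = 0.242). The bound set for arguing against 1 factor was all 8 bands, and 7 passed, so the comparison cannot tell. The bands by either list also draw on the same set of pairs. Excess reads over repeated sequence may give such peaks, and this stays open because input reads were not analysed here. No biological explanation was tested.

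Shared peaks showed no preference for gene ends: among 603 outside gene-poor bins, 40.5% lay within 500 bp of one, against a mean of 39.5% (range 34.5 to 44.1%) over 146 shifts of all peaks by 2000 to 20000 bp. Coordinates of another genome build may hide a preference, but in this scan the best shift was 2.82 SD and the unshifted share 0.598 SD above the mean of the shifts, so this explanation cannot be told apart from a protein without such a preference. This scan was chosen among many: in 45 other scans of gene ends the best shift reached 3.87 SD, and the unshifted share ran from -2.69 to 1.11 SD and lay below the mean in 37, at its lowest 18.1% against 26.2% for replicate 2 peaks scoring over 300 and within 300 bp. In 40 scans over 10 gene classes a shift passed 4 SD in 25, of which 24 were of classes holding under 2% of the peaks on average, where a few peaks can set the SD; protein-coding spans reached 3.22 SD. The unshifted share passed 4 SD in 2 of the 40, both from the single ribosomal RNA peak.

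Gene families were taken from symbols with a shared stem and at least 10 members. None of 151 families had more or fewer genes next to a shared peak after adjustment by the Benjamini-Hochberg method of Fisher's exact p (lowest adjusted p = 1), and 3 had an unadjusted p under 0.05. Strong peaks found in a single list were few. Replicate 1 had 4 unshared peaks with a score of at least 100, all in gene-poor bins, the highest on chromosome 4 from 3894550 to 3902153 with a score of 2032. Replicate 2 had 13, of which 1 lay in a gene-poor bin, the highest on chromosome 5 from 2951716 to 2955039 with a score of 475.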
